A study of Apis mellifera with 96 samples.

How the data were processed

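Per the labels, 1-day-old adult worker bees from 6 origin colonies (107, 109, 115, 122, 127 and 137) were spread evenly over 3 nuclear hives that held queens and honey frames. Nurses and foragers were caught on days 7 and 26 and frozen on dry ice. Total RNA of untreated whole bees went into libraries made together with an in-house TagSeq protocol, which sequences a tag near the 3' end of each transcript. The labels list 96 samples. Of these, 93 have a column in the count table. The negative control and the libraries of colony 127 nurses at day 7, replicates 2 and 3, have none and were not analysed here. The labels do not say whether a library holds 1 bee or a pool. Some libraries carry the replicate number of another library with the mark #2. Their counts differed from that other library by a median of 15.0 in chi-square per gene, against 16.9 between libraries of different numbers in a group. They were therefore treated as separate samples. Some pairs differed far less. Examples are the pair numbered 1 of colony 127 foragers at day 26 (1.94) and the pair numbered 3 of colony 107 nurses at day 7 (3.83). Another is the second library (#2) numbered 2 with replicate 3 of colony 122 nurses at day 26 (1.53). Whether such pairs are separate samples cannot be told from the counts, and the tests count them as independent.

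The deposited values are counts, that is, whole numbers of reads assigned to each gene, with no normalization. Per the submitters' processing notes, FastQC, HISAT2, SAMtools and DESeq2 were used, with versions not given. The counting program, the genome build and the annotation version are not given in the sources used here, so no coordinates are printed. The table holds 9935 genes and 5 entries for reads that were assigned to no gene. The latter stayed out of library totals and tests. On average 65.5% of the reads of nurses and 69.9% of the reads of foragers were counted as not aligned, and 14.5% and 11.2% fell on genes. Reads that aligned to more than 1 place, 3.70% in nurses and 3.02% in foragers, were not assigned to any gene, which can lower the counts of genes with close copies. Gene names came from the table itself. A reference table held 9920 of them as symbols and 13 mitochondrial genes by locus tag, and 2 were not found. A name other than a LOC number was given for 415 genes, of which 254 were tested. LOC genes are printed by that identifier since no table at hand gives their products.

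The library of colony 107 foragers at day 7, replicate 1, held 81736 counts, under 10% of the median of 1286245, and was left out. The 92 fitted libraries held 197805 to 2300891 counts on genes. A gene with no counts in a library of median size would be limited to about 3 counts, and such limits cover counting error only. Genes were kept with the filterByExpr function at a minimum count of 10 over the groups of role and day, which left 6753. Counts were scaled by TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood (glmQLFit with legacy=FALSE and robust=TRUE). The model had 1 mean for each of the 24 groups of colony, role and day and 68 residual degrees of freedom. Contrasts of these means gave the difference between foragers and nurses, the difference between days, the interaction of role and day, and tests over the 6 colonies. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. A log2 fold change is given with its standard error (SE). CPM values are counts scaled to a common library total with the same factors, given as mean and SD over libraries. P-values measure the spread between these libraries, and each colony stands for itself.

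Data were simulated with a single mean per gene, pooled over all libraries, and with the estimated spread. Genes and libraries were drawn independently, so the rates below leave out correlation between genes and between libraries. In these data the role contrast recovered 95% of genes changed 1.5-fold, with 5.41% false calls. The interaction contrast recovered 58% at 1.5-fold and 88% at 2-fold, with 3.95% false. The colony test recovered 81% and 93%, with 8.42% false. With no colony by role difference simulated, 0 genes were called.

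The groups, tests, gene lists as word patterns, rule for named genes and most alternatives were set before the data were examined. The rule names, for each main comparison, up to 5 genes with the largest rise and 5 with the largest fall that passed, had 1 sign in all 6 colonies and had a mean CPM of at least 5. For the interaction the condition on colonies was dropped. It adds the same for genes with a name other than a LOC number, up to 4 members of each list with the smallest adjusted p, and always Vg, Mrjp1, Hbg3 and the nicotinic receptor subunits. For colonies it names the 10 genes with the smallest p. CYP9Q1, CYP9Q2 and CYP9Q3, also on the rule, could not be matched to a gene name in the table. The patterns relied on product descriptions that the reference lacks. Lists were therefore rebuilt from symbols after the gene names, but no test, had been seen. The lists of opsins, of amine and neuropeptide signalling genes and of silk fibroins were added at that step. The neuronal list then took in members outside its planned pattern, such as Cac, Eaat-2, Camkii and GluCl. Carboxylesterases, UDP-glycosyltransferases, ABC transporters, digestive proteases and lipid synthesis enzymes could not be rebuilt. Silk fibroins (0 tested), germline and ovary genes (1 tested) and glutathione S-transferases (2 tested) had fewer than 3 members tested and got no list test.

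The other 21 lists were tested with camera (preset correlation 0.01) and fry in limma 3.58.1 on voom values with the same model, adjusted over the 21 lists of a comparison. Camera compares a list with the other genes. Fry asks whether members move, on balance, one way. Camera was repeated with a correlation estimated from the data. Over the lists and the 3 main comparisons it called 22 of 63 tests, and 6 of these held with the estimated correlation. These 6 are sugar processing enzymes and neuronal genes between roles, and sugar processing enzymes, venom genes, oxidative phosphorylation subunits and cuticle genes between days. None of the 22 turned direction.

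Residuals of libraries that share a replicate number across groups were compared to see whether numbers pair the samples. Their correlations between roles were -0.07, -0.06 and -0.04 for the 3 numbers, and between days 0.11, -0.04 and 0.09, so numbers were not used as blocks in the tests. The labels do not say whether a number stands for 1 of the 3 shared hives, so libraries of a number may not be independent. Alternatives were DESeq2 1.42.0 size factors, DESeq2 tests, other filters, older dispersion estimates, a replicate block, library total as covariate, summing of libraries, sums per colony, leaving out each replicate or colony, and 4 settings added after the data were seen.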

Results

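Transcripts of whole honey bee workers (Apis mellifera) were counted in nurses, which feed the brood, and in foragers, which collect nectar and pollen. Both roles were sampled on day 7 and day 26, so age and role can be separated, and the bees came from 6 origin colonies that shared 3 nuclear hives. Age runs together with the day of capture and the time in the hives, and the data cannot tell these apart. Changes with age below therefore stand for day 26 against day 7. The series concerns susceptibility to the insecticide imidacloprid and its link to life history. The sequenced bees were untreated per the labels, so the data describe bees without exposure. The fitted libraries were 22 of nurses and 22 of foragers at day 7, and 24 of nurses and 24 of foragers at day 26. Each group of colony, role and day held 4 libraries, apart from 3 for foragers at day 7 in colonies 107 and 127 and 2 for nurses at day 7 in colony 127.

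Library totals lay between 197805 and 2300891 counts on genes. Nurses held 1418720.0 ± 400876 counts (SD, n = 46) and foragers 1222810.0 ± 396804 (SD, n = 46), a difference beyond the spread of libraries (permutation p = 0.0117, adjusted p = 0.0219 over 15 tests of library measures). The share of reads that did not align was higher in foragers, at 69.9% ± 4.12 (SD, n = 46), than in nurses, at 65.5% ± 3.01 (SD, n = 46, permutation p = 1e-04, the smallest these permutations can give). It was also higher at day 26, at 68.8% ± 4.43 (SD, n = 48), than at day 7, at 66.6% ± 3.65 (SD, n = 44, permutation p = 4e-04, adjusted p = 0.0012). Whether this bears on the genes called between days was not tested. The first principal component of log2 CPM held 18.1% of the variance, and role took 45.2% of the variance of its scores and day 17.8%. Day took 59.3% of the second component and colony 32.6% of the third.

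**Figure D1:**
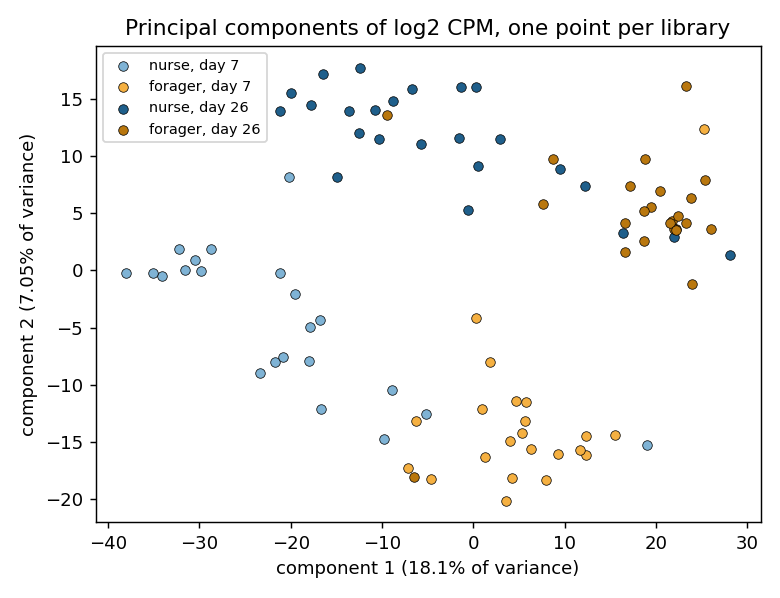
First and second principal components of log2 CPM, in arbitrary units, with 1 point per library for the 92 fitted libraries, coloured by role and day. Component 1 (18.1% of variance) separates mostly by role and component 2 (7.05%) mostly by day, and several libraries lie among those of the other role.

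The first comparison asked how foragers differ from nurses over both days and all colonies. Of the brood food gland proteins 6 of 9, and of the yolk and storage proteins all 7 tested, were lower in foragers, the same when adjusted over the list alone. Mrjp3, a major royal jelly protein that nurses secrete into brood food, was 30.7-fold lower in the fit (log2 fold change -4.94 ± 0.37 SE), at 848 ± 2096 CPM in foragers and 16364 ± 11418 in nurses (SD, n = 46 each). Folds are those of the fit, which averages the groups on the log scale, and the CPM means of Mrjp3 lay 19.3-fold apart. Among foragers, colony 122 day 26 replicate 2 held 14317 CPM of it and the next highest library 2987. Vg, the yolk precursor vitellogenin, was 8.43-fold lower in foragers, at 220.3 against 1803 CPM (-3.07 ± 0.31 SE). Hbg3, a gland alpha-glucosidase that splits nectar sucrose, was 3.79-fold higher in foragers, at 2932 ± 1214 against 987 ± 1128 CPM. All 3 directions held in each of the 6 colonies. In edgeR's test 2031 of 6753 genes differed, 1029 higher and 1002 lower in foragers, and 111 of them by over 2-fold. Of the 2031, 1390 (68.4%) had the same sign in all 6 colonies, as did 1663 (24.6%) of all 6753 tested. The 2031 were called on the mean of these same colonies, which favours 1 sign.

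Among the brood food gland proteins all 9 tested members differed, 6 lower and 3 higher in foragers (9 when adjusted over the list alone). The list as a whole fell against the other genes (camera adjusted p = 1.09e-05), with adjusted p = 0.0659 with an estimated correlation. Mrjp2 (-4.12 ± 0.33), Mrjp4 (-4.11 ± 0.35) and Mrjp7 (-3.72 ± 0.28) fell with Mrjp3, and Mrjp1, the most abundant of them, fell from 60988 to 8369 CPM, 7.29-fold in these means and 11.5-fold in the fit (-3.52 ± 0.32). Mrjp6 went the other way, at 0.97 ± 0.21. The 3 sugar processing enzymes rose, and all 3 passed when adjusted over the list alone. They are the alpha-glucosidases Hbg3 (1.92 ± 0.20), AGLU2 (0.93 ± 0.10) and Hbg2 (0.39 ± 0.12). The list rose with either correlation (adjusted p = 2.32e-05, and adjusted p = 0.0159 with an estimated correlation). All 7 yolk and storage proteins were lower in foragers, also when adjusted over the list alone (adjusted p = 1.49e-06, and adjusted p = 0.0514 with an estimated correlation). Besides Vg these include the lipoprotein Vhdl (-4.32 ± 0.40) and the storage hexamerins Hex110 (-4.28 ± 0.43) and Hex70a (-3.56 ± 0.35).

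**Figure D2:**
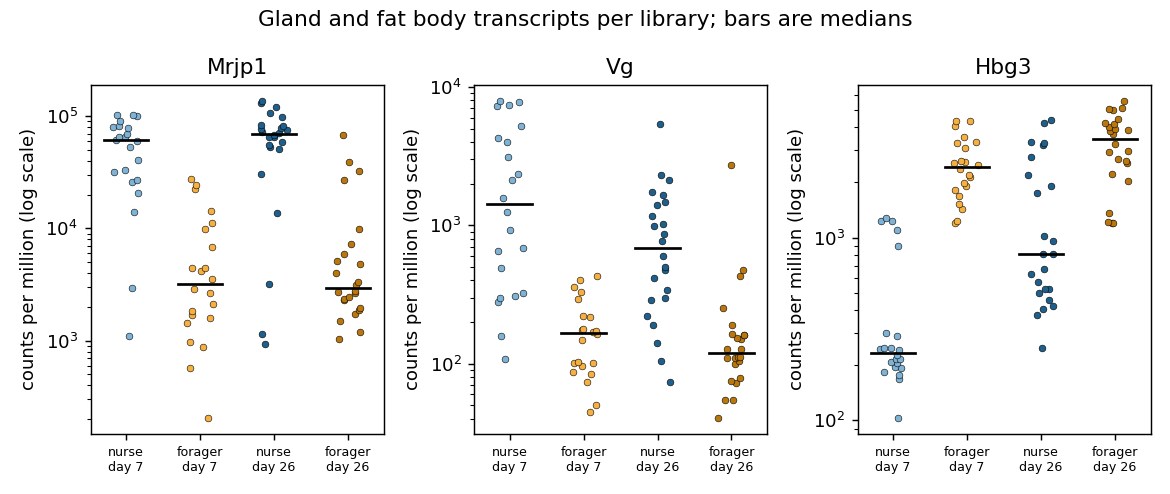
CPM per library of gland and fat body transcripts on a log scale, by role and day, with the median of each group as a bar (22 or 24 libraries per group). Median Mrjp1 was 60784 and 69610.2 CPM in nurses at days 7 and 26 and 3213 and 2975 CPM in foragers, and some libraries of each role lie within the range of the other.

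Transcripts of nerve and eye were higher in foragers. In whole bees a rise within these tissues, here or between days below, cannot be told apart from a larger share of them in the RNA. Of 9 neuronal genes 7 rose (9 when adjusted over the list alone), and the list was called with both correlations (adjusted p = 1.27e-05, and adjusted p = 0.0159 with an estimated correlation). They include Cac, a voltage-gated calcium channel (0.79 ± 0.16), the glutamate transporter Eaat-2 (0.75 ± 0.13), the kinase Camkii (0.66 ± 0.11) and the glutamate-gated chloride channel GluCl (0.62 ± 0.08). The 3 opsins of the photoreceptors rose by about the same amount, Lop1 at 0.36 ± 0.09, Blop at 0.41 ± 0.11 and Uvop at 0.41 ± 0.08, and all 3 passed when adjusted over the list alone. The opsin list had adjusted p = 0.0136, and adjusted p = 0.0756 with an estimated correlation. Of the nicotinic acetylcholine receptor subunits, which form the target of imidacloprid, 4 were tested. nAChRb2 rose by 0.64 ± 0.13 and nAChRa9 by 0.37 ± 0.10. nAChRa6 (0.37 ± 0.17, adjusted p = 0.0966) and nAChRa8 (0.04 ± 0.08, adjusted p = 0.760) did not pass, and 3 passed when adjusted over the list alone. Their list test lay at the threshold, with adjusted p = 0.0497, and adjusted p = 0.117 with an estimated correlation. It was 0.0501 with DESeq2 size factors and 0.0531 with a replicate block.

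**Figure D3:**
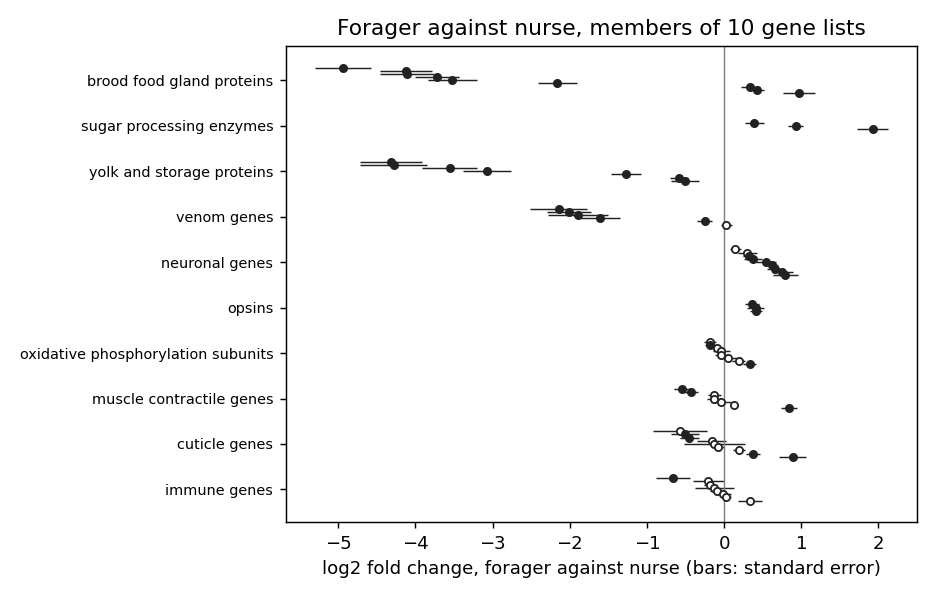
Log2 fold change, forager against nurse, of each tested member of 10 gene lists, with its standard error as a bar, from the fit to 92 libraries. Filled points passed (adjusted p under 0.05) and open points did not, and the yolk and storage proteins lie below 0 while the sugar processing enzymes and opsins lie above it.

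Venom transcripts were lower in foragers for 5 of 6 members, also when adjusted over the list alone (adjusted p = 0.00299, and adjusted p = 0.09996 with an estimated correlation). They include melittin (Melt, -1.61 ± 0.26), Apamin (-2.01 ± 0.29), the mast cell degranulating peptide Mcdp (-2.14 ± 0.37) and the phospholipase Pla2 (-1.89 ± 0.39). All 7 cytosolic ribosomal proteins were lower by small amounts, such as RpL32 (-0.31 ± 0.05), with 7 adjusted over the list alone, adjusted p = 1.27e-05, and adjusted p = 0.0659 with an estimated correlation. These falls ran beside the higher share of reads that did not align in foragers. Hormone-related transcripts moved singly. Kr-h1, a transcription factor that juvenile hormone induces, rose (1.18 ± 0.16), as did the nuclear receptor E75 (0.72 ± 0.16) and the corazonin receptor Crzr (0.94 ± 0.15), and the juvenile hormone esterase Jhe fell (-1.44 ± 0.18). The endocrine list went both ways, with 2 members higher and 2 lower of 5 (2 higher and 3 lower adjusted over the list alone; adjusted p = 0.985).

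Cytochrome P450s, a family of enzymes of which some act in detoxification, went both ways between roles. Of the 5 cytochrome P450s tested, Cyp6as5 (0.65 ± 0.11) and CYP6AS13 (0.37 ± 0.06) were higher in foragers, and CYP6AS11 (-0.96 ± 0.12) and Cyp4g11 (-0.47 ± 0.09) were lower. CYP6AQ1 did not pass (-0.20 ± 0.10, adjusted p = 0.133), and the list was not called (4 adjusted over the list alone, adjusted p = 0.916). The 4 CYP6 members alone gave adjusted p = 0.916, with 2 higher and 1 lower by either adjustment. Odorant-binding and chemosensory proteins were split, with 7 of 23 higher and 5 lower, the same when adjusted over the list alone (adjusted p = 0.985). Obp14 (-2.64 ± 0.33) and Obp17 (-1.26 ± 0.13) had the largest falls of its named members. The calls of Hbg2, Lop1, Blop and nAChRa9 were lost in at least 1 setting that used fewer libraries. Those of Melt, Mcdp and Pla2 were lost when counts were summed per colony, role and day.

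Taken day by day, foragers and nurses differed in 1366 genes at day 7 (618 higher, 748 lower) and in 1196 at day 26 (592 higher, 604 lower). The day 7 count fell when replicate numbers or colonies were left out. In those settings the day 26 count ran from below to above 1196, as given in the closing part. Of the 628 called at both days, 620 had the same direction, where 121 would be met by chance from the counts called. The log2 fold changes of the days, which come from different bees, had a Pearson correlation of 0.746 across genes, which are not independent replicates. Mrjp3 changed by -5.59 ± 0.55 at day 7 and -4.29 ± 0.47 at day 26 on the log2 scale. Vg changed by -3.66 ± 0.46 at day 7 and -2.49 ± 0.41 at day 26, and the difference between the days did not pass (adjusted p = 0.371). Hbg3 was 5.91-fold higher in foragers at day 7 and 2.44-fold higher at day 26 (adjusted p of the difference 0.0897).

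The comparison of day 26 with day 7 asked what differs between workers caught on these days, over both roles. Transcripts of the cuticle, of venom and of the respiratory chain were lower at day 26. Apd-1, a cuticle protein of the apidermin family, fell 84.6-fold in the fit (log2 fold change -6.40 ± 0.32 SE), with medians of 442 CPM at day 7 and 3.08 at day 26. Its means were 437 ± 298 CPM (SD, n = 44) and 27.4 ± 154 (SD, n = 48), only 15.9-fold apart, as 1 library, colony 115 forager day 26 replicate 1, held 1068 CPM at day 26 and the next highest 43.6. It is 1 of 7 libraries whose mitochondrial profile departs from their colony. Pla2, the venom phospholipase, fell 20.7-fold in the fit, and its means of 465 and 35.4 CPM lay 13.1-fold apart, with 753 CPM in that library and 168 in the next highest at day 26. Uqcr11, a subunit of respiratory complex III, fell 2.23-fold, from 778 ± 259.8 to 349.7 ± 108 CPM. Hbg2, an alpha-glucosidase, rose 1.84-fold, from 1017 to 1894 CPM. Each of these had the same direction in all 6 colonies. In all, 1764 genes differed, 924 higher and 840 lower at day 26, with 78 over 2-fold, and 1096 of the 1764 (62.1%) had the same sign in all 6 colonies.

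Of 9 cuticle genes tested, 6 fell and 2 rose, the same when adjusted over the list alone (adjusted p = 1.60e-05, and adjusted p = 0.0128 with an estimated correlation). The falls were led by Apd-1, Apd-3 (-5.38 ± 0.37), Apd-2 (-1.79 ± 0.18) and the chitin-binding Cpap3-b (-1.47 ± 0.18). Apd-3 fell 41.6-fold in the fit and 15.0-fold in its CPM means, with 1362 CPM in the same library and 138 in the next highest at day 26. Of 6 venom genes 4 fell, also adjusted over the list alone. They are Pla2 (-4.37 ± 0.39), Mcdp (-4.15 ± 0.38), Apamin (-2.46 ± 0.29) and Melt (-2.39 ± 0.26; list adjusted p = 3.06e-06, and adjusted p = 0.0130 with an estimated correlation). Of 8 nuclear subunits of oxidative phosphorylation 6 fell, also adjusted over the list alone (adjusted p = 2.35e-07, and adjusted p = 0.0130 with an estimated correlation). Besides Uqcr11 they include Cox6b1 (-0.93 ± 0.07) and Cox6c (-0.83 ± 0.08) of complex IV and the ATP synthase subunit ATP5G2 (-0.52 ± 0.08). The mitochondrially encoded genes fell too, with 10 of 13 lower, also adjusted over the list alone. Examples are COX1 (-0.97 ± 0.09) and COX2 (-1.36 ± 0.13). Their list test gave adjusted p = 2.48e-06, and adjusted p = 0.185 with an estimated correlation. The share of counts on these 13 genes was 6.69% ± 2.47 (SD, n = 44) at day 7 and 3.32% ± 1.28 (SD, n = 48) at day 26 (permutation p = 1e-04, the smallest these permutations can give). Muscle genes were split, with 5 lower, such as the troponins TpnCI (-0.91 ± 0.09) and TpnT (-0.54 ± 0.10), and 2 higher, by either adjustment (adjusted p = 0.00651, and adjusted p = 0.0670 with an estimated correlation).

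**Figure D4:**
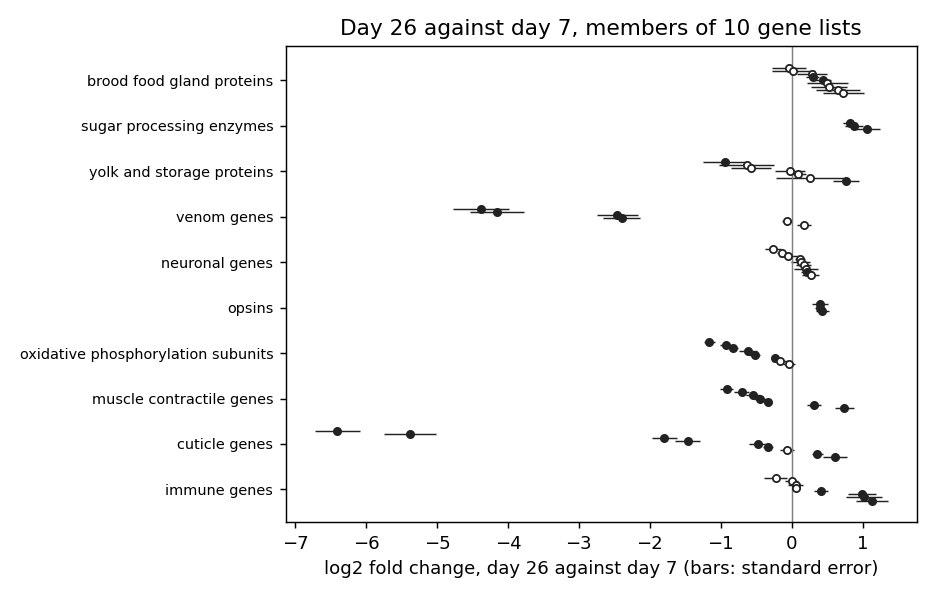
Log2 fold change, day 26 against day 7, of each tested member of 10 gene lists, with its standard error as a bar, from the fit to 92 libraries. Filled points passed (adjusted p under 0.05) and open points did not, and the lowest cuticle and venom members lie at -6.40 and -4.37.

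The genes that rose with age include sugar, immune, visual and cytochrome P450 transcripts. All 3 sugar processing enzymes rose, also adjusted over the list alone (adjusted p = 6.54e-05, and adjusted p = 0.0130 with an estimated correlation), Hbg2 by 0.88 ± 0.12, AGLU2 by 0.82 ± 0.10 and Hbg3 by 1.05 ± 0.19. Of 8 immune genes 4 rose, by either adjustment, among them the peptidoglycan recognition protein Pgrp-s2 (1.13 ± 0.22) and the antimicrobial peptides Apid1 (1.02 ± 0.26) and Def1 (0.99 ± 0.20). A few libraries lay far above the rest, as 2 of colony 137 at day 26 held 12554 and 12135 CPM of Apid1 and 30767 and 32073 of Def1. The medians at days 7 and 26 were 688 and 837 CPM for Apid1 and 3300 and 5323 for Def1. Pgrp-s2 reached 20127 CPM in 1 of these 2, where its medians were 1179 and 1875. The immune list as a whole was not called (adjusted p = 0.0850). The 3 opsins rose, also adjusted over the list alone (adjusted p = 0.00930, and adjusted p = 0.0670 with an estimated correlation), Lop1 by 0.43 ± 0.09, Uvop by 0.40 ± 0.08 and Blop by 0.39 ± 0.11. Of 5 cytochrome P450s 4 rose, CYP6AQ1 by 0.72 ± 0.10, Cyp6as5 by 0.42 ± 0.11, Cyp4g11 by 0.31 ± 0.09 and CYP6AS13 by 0.23 ± 0.06. Adjusted over the list alone 4 rose and 1 fell (adjusted p = 0.0241, and adjusted p = 0.0777 with an estimated correlation). The fatty acyl-CoA reductase FAR1 rose by 1.01 ± 0.09, and the mitochondrial superoxide dismutase Sod2 fell, at -0.74 ± 0.11. Of the nicotinic subunits, nAChRa6 (0.46 ± 0.17) and nAChRa8 (0.26 ± 0.08) rose, 2 of 4 by either adjustment. nAChRa9 (0.20 ± 0.10, adjusted p = 0.128) and nAChRb2 (0.02 ± 0.13, adjusted p = 0.915) did not pass, and the list gave adjusted p = 0.184. Vg and Mrjp1 did not pass between days (-0.58 ± 0.28, adjusted p = 0.129, and 0.50 ± 0.29, adjusted p = 0.192). The calls of nAChRa6, nAChRa8 and Cyp4g11 were lost when counts were summed per colony, role and day, and those of Apid1, Lop1, Blop, Cyp6as5 and CYP6AS13 in at least 1 setting with fewer libraries.

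Within nurses 907 genes differed between days (440 higher, 467 lower at day 26), and within foragers 1274 (655 higher, 619 lower). Of the 462 called in both roles, 458 had the same direction, where 85.5 would be met by chance, and the log2 fold changes of the roles correlated at 0.681 across genes. Age and role moved many genes alike. Of 659 genes called in both, 510 had the same sign for forager and for day 26 and 149 the opposite. About 265 each would be met by chance if genes were independent, which they are not. The correlation across genes was 0.298 from the fitted changes and 0.353 from log2 CPM. Simulated libraries without either effect gave 0.0197 on average, with 95% of 200 draws between -0.205 and 0.270. These draws hold no role or age effect, so they cannot show what unrelated role and age effects would give. Hbg3, AGLU2, Hbg2, E75, Kr-h1 and the opsins were higher both in foragers and at day 26, and Melt, Apamin, Mcdp and Pla2 lower in both.

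The interaction of role and day asked which genes differ between roles by another amount at day 26 than at day 7. In this contrast 56 genes passed, 33 with a larger and 23 with a smaller forager minus nurse value at day 26 (871 at an unadjusted p under 0.05). Obp7, an odorant-binding protein, was lower in foragers than in nurses at day 7, at 5.95 ± 3.66 against 12.5 ± 6.81 CPM (SD, n = 22 each), and higher at day 26, at 7.66 ± 4.29 against 3.45 ± 3.35 (SD, n = 24 each; difference 2.07 ± 0.42 on the log2 scale, adjusted p = 0.00359). CSP3, a chemosensory protein, was lower in foragers at day 7, at 6858 against 11129 CPM, and close to nurses at day 26, at 7516 against 8138 (0.58 ± 0.13, adjusted p = 0.0122). TpnCIIIa, a calcium-binding troponin, went from 247 CPM in nurses and 596 in foragers at day 7 to 419.5 and 559 at day 26 (-0.81 ± 0.20, adjusted p = 0.0223). LOC725114, whose product the reference does not give, was higher in foragers at day 7 (4977 against 964 CPM) and lower at day 26 (2515 against 5132 CPM; -2.94 ± 0.47, adjusted p = 7.73e-05).

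Of the 23 odorant-binding and chemosensory proteins, Obp7 and CSP3 passed (3 adjusted over the list alone), and the list moved up at day 26 (adjusted p = 0.00942, and adjusted p = 0.403 with an estimated correlation). Of the 13 mitochondrially encoded genes 5 passed and 11 adjusted over the list alone (adjusted p = 9.01e-05, and adjusted p = 0.456 with an estimated correlation). They include COX3 (2.31 ± 0.50), ND3 (2.07 ± 0.45), ND4 (1.88 ± 0.45) and ATP6 (1.79 ± 0.43). These 4 calls rest on the 7 libraries that depart from their colony. Without them, a setting chosen after the data were seen, COX3 stood at 0.25 (adjusted p = 0.399), ND3 at 0.42 (0.467), ND4 at 0.22 (0.579) and ATP6 at 0.20 (0.585), and the list gave adjusted p = 0.746. The list tests of sugar processing enzymes (down, adjusted p = 0.0171, and adjusted p = 0.403 with an estimated correlation), yolk and storage proteins (up, 0.0172, and adjusted p = 0.470 with an estimated correlation), oxidative phosphorylation subunits (up, 0.0172, and adjusted p = 0.456 with an estimated correlation) and cytosolic ribosomal proteins (up, 0.0171, and adjusted p = 0.456 with an estimated correlation) were called with no member passing over all genes. Adjusted over the list alone, 2 sugar processing enzymes passed and 0 members of the other 3 lists by edgeR. Without the 7 libraries the sugar and oxidative phosphorylation lists gave adjusted p = 0.0629 and 0.409. Nicotinic subunits and P450s had no member past the threshold over all genes in edgeR's test of this contrast, and their lists gave adjusted p = 0.616 and 0.226. Each of the 12 interaction calls named here or in the closing part was lost in at least 1 setting with fewer libraries, that of Obp7 without replicate number 2 alone. The count of 56 moves with the processing, to 12 with the second library of a number summed with the first and 14 with counts summed per colony, role and day.

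The test between origin colonies asked which transcripts depend on where the bees came from. It called 1203 genes (2168 at an unadjusted p under 0.05). All 13 mitochondrially encoded genes differed, also adjusted over the list alone (Fisher's exact adjusted p = 3.62e-09 against the other genes), and 7 of 8 nuclear subunits of oxidative phosphorylation did (8 adjusted over the list alone; Fisher's exact adjusted p = 0.000398). Fisher's test takes genes as independent, so its p-values can be too small for genes that move together. They do not measure the spread between libraries. COX2 ranged from 3816 CPM in colony 115 to 16028 in colony 109, and ND3 from 51.3 to 318. Against the mean of the other 5 colonies, colony 115 stood at -4.81 ± 0.48 for ND4L, -3.74 ± 0.43 for COX3 and -3.24 ± 0.37 for ND4 on the log2 scale. ND2 showed no such change in it, at 0.23 ± 0.12. These colony 115 values include its 3 libraries that depart from it, which held 5604 to 13531 COX3 counts where its other 13 held 31 to 112. The gap of those 13 in COX3 is therefore larger than the value given. LOC113218735 had the smallest p (adjusted p = 1.38e-19), with 555 CPM in colony 109 and 6032 to 8631 in the others. TpnCIIIb, a troponin, went from 23.5 CPM in colony 107 to 76.0 in colony 127 (adjusted p = 9.08e-09). Vg (0.160) and Mrjp1 (0.0808) did not pass between colonies and Hbg3 did (adjusted p = 0.0298). The libraries of a colony carry consecutive numbers, so the labels do not separate colony from position in that order. The share of reads not aligned also differed between colonies, from 65.3% in 137 to 69.8% in 115 (permutation p = 0.0049, adjusted p = 0.0105). So did the share on genes, from 11.6% in 115 to 14.7% in 137 (permutation p = 6e-04, adjusted p = 0.0015). Whether these shares bear on the 1203 genes was not tested. The count of 1203 was 281, 377 and 792 without replicate number 2, 3 or 1, and 659 with the second library of a number summed with the first.

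The ratio of COX2 to COX3 counts differed between some of the colonies. Outside the 7 libraries mentioned above, its median was 1.10 in colony 107, 3.92 in colony 109, 45.7 in colony 115, 1.05 in colony 122, 2.97 in colony 127 and 1.12 in colony 137. In colony 115 it ranged from 20.2 to 114 over 13 libraries. Colonies 109 (2.71 to 4.78) and 127 (2.06 to 4.51) overlapped, as did colonies 107 (0.806 to 1.40), 122 (0.848 to 1.31) and 137 (0.756 to 1.78).

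**Figure D5:**
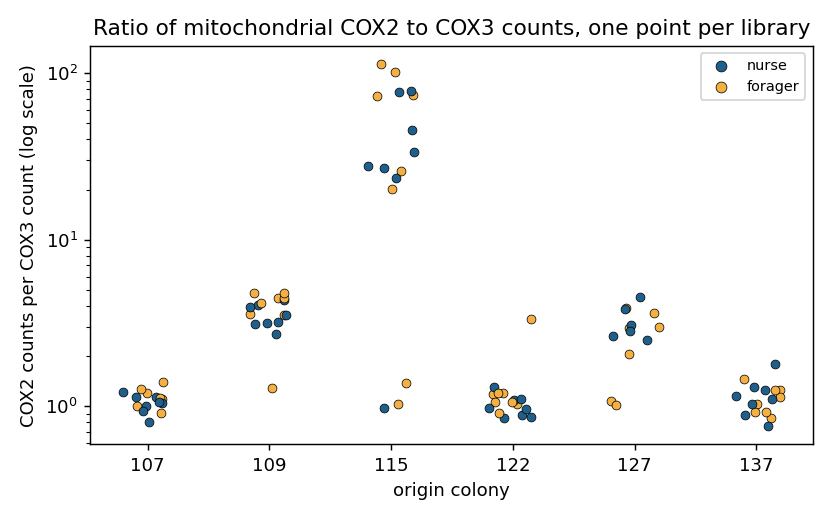
Ratio of COX2 to COX3 counts on a log scale, with 1 point per library, by origin colony and coloured by role. Colony 115 has a median of 45.7 over 13 libraries, and 3 of its libraries lie near 1, among those of colonies 107, 122 and 137.

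Whether the difference between roles depends on colony was tested by the colony by role interaction. It called 0 genes in edgeR, with 512 at an unadjusted p under 0.05 and 12 in DESeq2. Adjusted over a list alone, 4 of 6 venom genes and 3 of 9 cuticle genes passed. So did 1 member each of the brood food, nicotinic and CYP6 lists, and none of the other lists had a member that passed. Tested within single colonies, foragers and nurses differed in 994 genes in colony 107, 379 in 109, 56 in 115, 11 in 122, 16 in 127 and 414 in 137. The interaction test does not show that these differ, and all of these counts move with the processing. Leaving out a replicate number gave as few as 170 in colony 107, 34 in 109 and 0 in 115, 122, 127 and 137, and DESeq2 gave 90 in 122 and 52 in 127. The lowest Mrjp1 in a nurse library was 31578 CPM in colony 107, 2935 in 109, 1112 in 115, 927 in 122, 3198 in 127 and 13677 in 137. Whether nurse libraries with so little Mrjp1 lower the counts of single colonies was not tested. The change in role of each colony correlated across genes with that of the other 5 at between 0.654 in colony 122 and 0.813 in colony 137. Mrjp3 and Vg were lower, and Hbg3 higher, in foragers of every colony. The colony by day interaction called 3 genes at the same adjusted p of 0.0386 (704 at an unadjusted p under 0.05). Over the alternatives this count ran from 0 to 75. The 3 are Apd-1, LOC100578581 and LOC413517, named because the count is small and after their values were seen. Apd-1 fell with age in all 6 colonies, from -3.28 in colony 115 to -9.25 in colony 109 on the log2 scale, where colony 115 includes the library of 1068 CPM at day 26. That library is 1 of the 7 that depart from their colony, and all 3 calls held without the 7, among 30. Adjusted over a list alone, 4 of 6 venom genes, 5 of 8 oxidative phosphorylation subunits and 4 of 9 cuticle genes passed for colony by day. So did 2 of 5 cytochrome P450s and 1 member each of the muscle, amine and mitochondrial lists.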

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

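The tests on mitochondrial transcripts by colony, on library totals, on the day of the departing libraries and on a trend along library numbers were chosen only after the results they bear on were seen.

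Vg, Mrjp1, Hbg3 and library totals were searched for single libraries far from the other 3 of their group, by the gap to the nearest library over the whole range. Of 84 tests 12 passed, where about 4.2 are met by chance. For Mrjp1 they are colony 115 nurse day 7 replicate 3 (ratio 0.945, at a log2 CPM of 10.1 where the others lay at 16.0 to 16.3), colony 115 nurse day 26 replicate 2 (0.958), colony 122 nurse day 26 replicate 2 (0.898), colony 127 nurse day 26 replicate 3 (0.894) and colony 137 nurse day 7 replicate 1 (0.923), each lower than the other nurses of its group. For Hbg3 they are the second library (#2) numbered 2 of colony 122 nurses at day 7 (0.902), colony 137 nurse day 7 replicate 1 (0.926) and colony 137 nurse day 26 replicate 3 (0.859), each higher than the other nurses of its group. For Vg they are the second library (#2) numbered 3 of colony 107 nurses at day 26 (0.891, lower), colony 115 forager day 26 replicate 1 (0.938, higher), colony 137 nurse day 7 replicate 1 (0.869, lower, at 8.28 against 12.3 to 13.0) and colony 137 forager day 26 replicate 1 (0.845, lower). Colony 137 nurse day 7 replicate 1 thus stood apart in Vg, Mrjp1 and Hbg3. No library was moved to another role for this, and no explanation of these libraries was tested.

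The test of the difference between days in the forager minus nurse value called 56 genes. Named among them are LOC725114 (-2.94), LOC726737 (-2.16), LOC727193 (-1.63), LOC113218518 (-1.61), LOC107965279 (-1.22) and TpnCIIIa (-0.81), and, in the other direction, CSP3 (0.58), ATP6 (1.79), ND4 (1.88), Obp7 (2.07), ND3 (2.07) and COX3 (2.31). Without the 7 libraries described below, COX3 (0.25), ND3 (0.42), ND4 (0.22) and ATP6 (0.20) came close to 0 and no longer passed. The values of 3 others moved less but missed the threshold too. LOC726737 went from -2.16 ± 0.53 to -2.03 ± 0.57 (adjusted p = 0.0638), LOC727193 from -1.63 ± 0.42 to -1.35 ± 0.44 (0.104) and LOC113218518 from -1.61 ± 0.41 to -1.56 ± 0.43 (0.0584). List tests of the same contrast were called for sugar processing enzymes (adjusted p = 0.0172, and 0.403 with an estimated correlation), yolk and storage proteins (0.0172, and 0.470), odorant-binding and chemosensory proteins (0.00942, and 0.403), oxidative phosphorylation subunits (0.0172, and 0.456), cytosolic ribosomal proteins (0.0172, and 0.456) and mitochondrially encoded genes (9.01e-05, and 0.456). The change with age differed between colonies for Apd-1, LOC100578581 and LOC413517 (adjusted p = 0.0386 each). Among reads that the tests do not use, 69.9% of those of foragers did not align, above the 65.5% of nurses.

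The mitochondrially encoded genes differed between colonies gene by gene, from -4.81 for ND4L to 0.23 for ND2 in colony 115 against the other 5. These values include the 3 departing libraries of colony 115. A fall by the same amount in all mitochondrial transcripts of colony 115 is argued against, since the SD of the 13 log2 fold changes was 1.54 where their median SE was 0.354. A lower total is not, as their share of counts was 2.86% ± 2.30 (SD, n = 16) in colony 115. In the other colonies the mean share was 4.52% to 5.87% (permutation p over the 6 colonies 1e-04). Colony took 95.7% of the variance of the log2 ratio of COX2 to COX3 over 85 libraries, where role and day took 3.48% and shuffled colony labels at most 34.8% (permutation p = 1e-04, the smallest these permutations can give), and 71.4% over all 92 (shuffled at most 25.4%), with the 7 that depart from their colony in these transcripts. Either share is in line with a sequence of the maternal line that differs from the reference so that fewer tags align, but that explanation cannot be told apart from a difference in the amount of single transcripts, since the reads are not at hand. A difference in transcript processing between maternal lines, which origin colony would give, stays open and was not tested.

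The 7 libraries that depart from the mitochondrial profile of their colony are colony 109 forager day 7 replicate 3, in colony 115 the second libraries (#2) numbered 2 of nurses at day 7 and of foragers at day 26, and forager day 26 replicate 1, colony 122 forager day 7 replicate 3, and colony 127 forager day 7 replicate 1 and forager day 26 replicate 2. On 200 nuclear genes chosen without them, only 1 of the 7 was placed in its labelled colony against 68 of 85 other libraries (80.0%, where chance gives 16.7%), a one-sided Fisher's exact p of 0.000823. These bees may therefore come from another origin colony than their label says, as a hypothesis, and for the 5 placed in their labelled day by nuclear genes, a bee taken for one of another colony in the shared hives and an exchange of tubes would look alike here. A bee of another colony caught on the labelled day is argued against for the other 2, since colony 115 forager day 26 replicate 1 had a score of -1.84, on a scale from the mean of day 7 (-1) to that of day 26 (1), and colony 122 forager day 7 replicate 3 one of 1.12, where all other libraries lay between -1.90 and 0.116 at day 7 and between 0.495 and 1.78 at day 26, and a wrong label or an exchange of tubes stays open for these 2. Few counts cannot be told apart as a contributor, since just 3 of the 7 have totals above 1085177 counts, a level at or under which 22 of the other 85 lie (medians 1013564 and 1304607, permutation p = 0.0642), although 0 of these 3 and 16 of those 22 were placed in their own colony.

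The last pattern is the 1203 genes that differ between colonies, whose libraries were numbered in consecutive runs by colony. Library totals are argued against as the cause, since 1278 genes were called with the log10 total as a covariate and 1133 of the 1203 (94.2%) were shared. By their nuclear genes, 6 of the 7 departing libraries were placed outside the colony of their own run. This cannot decide on a fixed difference between runs of library numbers, which stays open. A wrong label or an exchange of tubes, left open above, could carry the difference of another run along with the library. A gradual trend along library numbers is a candidate explanation for part of the pattern. Steadily ordered colony means were found for 44 genes, 32 rising and 12 falling (3.66%, where chance gives 0.278%). Only 1 of 360 colony orders, the real one, gave that many, while the highest other order gave 37 and the median 2. Genetic differences between the colonies stay open for the rest and were not tested.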

How the results depend on the processing

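The settings without the 7 departing libraries, without the 2 fitted libraries of lowest total, and without the mitochondrial or the Mrjp genes were chosen after the data were seen. With the replicate block the counts were 2007 between roles, 1751 between days and 52 for role by day. The counts between roles (2031) and between days (1764) stayed within 1.5 times in every setting run, apart from the day count without replicate number 2. Among the values of named genes under these settings, 3285 kept direction and side of the threshold, 217 kept direction but no longer passed, 5 came to pass and 23 turned sign. Where a setting leaves out libraries, colonies or sums, fewer samples are part of its construction, and for the other settings the cause was not tested. Depth limits weakly expressed genes most, since 6753 of 9935 genes had enough counts to be tested.

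Leaving out each of the 3 replicate numbers in turn keeps 57 to 61 libraries. Without number 1 colony 127 drops out, so the role counts within single colonies come from leaving out numbers 2 and 3 alone. Without number 3 a group of 1 library is assumed to vary like the others. Over these settings, and for the first 7 counts also over leaving out each colony in turn, the counts ran from 1376 to 1973 between roles, 754 to 1342 at day 7, 495 to 1253 at day 26, 822 to 1628 between days, 389 to 837 in nurses, 436 to 1180 in foragers and 11 to 48 for role by day. They ran from 281 to 792 between colonies, 0 to 2 for colony by role and 0 to 23 for colony by day. Within single colonies the role counts ran from 170 to 428 in colony 107, 34 to 63 in 109, 0 to 89 in 115, 0 to 17 in 122, 0 to 8 in 127 and 0 to 443 in 137.

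The role by day count of 56 was 36 without colony 107, 20 without 109, 26 without 122, 35 without 127 and 27 without 137. It was 12 with the second library of a number summed with the first and 14 with counts summed per colony, role and day. Without the 7 departing libraries it was 67, of which 41 were shared. The role count at day 26 was 614 without colony 107, and the colony count was 659 with second libraries summed. Of the 22 list calls, 6 were left with the estimated correlation.

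The colony by role count of 0 was 12 with DESeq2. The colony by day count of 3 was 5 with DESeq2 size factors, with a filter per group, without mitochondrial genes and without Mrjp genes. It was 0 with no filter, with the older dispersions, with the replicate block and with second libraries summed. It was 12 with the total as covariate, 30 without the 7 departing libraries, 17 without the 2 libraries of low total and 75 with DESeq2. The role count within colony 109 was 122 with the covariate and 190 with second libraries summed, within 115 it was 13 with second libraries summed and 14 without the departing libraries, and within 137 it was 167 with second libraries summed. Within 122 it was 17 with size factors, 0 with no filter, 5 with the block, 4 with second libraries summed, 90 with DESeq2, and 0 without the departing libraries, the low ones or the Mrjp genes. Within 127 it was 7 with no filter, older dispersions or the covariate, 5 with the block or second libraries summed, 52 with DESeq2, 10 without mitochondrial genes, and 0 without the departing libraries or the Mrjp genes.

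The 23 values that turned sign belong to genes that passed in neither setting. Over the settings that leave out replicate numbers or colonies, the log2 change of nAChRb2 between days ran from -0.15 to 0.16, and that of nAChRa8 between roles from -0.028 to 0.15. For role by day they ran from -0.45 to 0.83 for Mrjp1, -0.049 to 0.31 for nAChRa6 and -0.080 to 0.14 for nAChRa8. Of the other settings, nAChRb2 between days was -0.0037 with the block, Mrjp1 for role by day -0.11 with all 93 libraries, and nAChRa6 -0.014 with the covariate. For role by day nAChRa8 was -0.0026 with older dispersions, -0.0087 with second libraries summed, -0.018 with sums per colony, -0.021 without the departing libraries and -0.053 without the low ones.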

Other observations

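The comparisons of regrouped libraries below were planned, and the list test without the 7 departing libraries was added after the data were seen. Gene groups with fewer moving members complete the picture. Among 8 antioxidant enzymes, 2 were higher in foragers and 3 lower (2 and 4 adjusted over the list alone), such as the methionine sulfoxide reductase MsrA (0.41 ± 0.13) and the superoxide dismutase Sod1 (-0.25 ± 0.04). With age 4 rose and 2 fell by either adjustment, such as catalase (Cat, 0.25 ± 0.06) and Sod2 (-0.74 ± 0.11), and the list was called in neither comparison (adjusted p = 0.232 and 0.772). Of 4 heat shock proteins, Hsp90 (-0.38 ± 0.11) and Hsc70-4 (-0.21 ± 0.07) were lower in foragers (3 adjusted over the list alone), and Hsc70-5 rose with age (0.48 ± 0.05; 1 adjusted over the list alone), with list values of 0.136 and 0.143. The clock gene Per fell with age (-0.39 ± 0.08) and was 1 of 3 circadian and foraging genes to change (1 rising and 2 falling adjusted over the list alone). No member of that list passed between roles in edgeR, at either adjustment, and its list values were 0.958 and 0.484. Of 5 amine and neuropeptide signalling genes, Crzr rose in foragers and the octopamine receptor Oa1 rose with age (0.53 ± 0.12), 1 each by either adjustment (0.617 and 0.530).

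The remaining lists between roles gave adjusted p = 0.897 for immune genes (1 of 8 lower, by either adjustment), 0.985 for oxidative phosphorylation subunits (1 higher and 1 lower of 8, and 2 each adjusted over the list alone), 0.916 for muscle genes (1 higher and 2 lower of 7, and 2 each adjusted over the list alone), 0.985 for cuticle genes (2 higher and 2 lower of 9, and 3 and 2 adjusted over the list alone) and 0.165 for mitochondrially encoded genes (1 of 13 lower, by either adjustment; 0.00362 without the 7 departing libraries, a setting added after the data were seen). Between days they gave 0.127 for brood food gland proteins (2 of 9 higher, and 3 adjusted over the list alone), 0.772 for yolk and storage proteins (1 higher and 1 lower of 7, by either adjustment), 0.350 for endocrine genes (2 of 5 higher, by either adjustment), 0.602 for neuronal genes (1 of 9 higher, and 0 adjusted over the list alone), 0.621 for odorant-binding and chemosensory proteins (4 higher and 6 lower of 23, by either adjustment) and 0.852 for cytosolic ribosomal proteins (2 of 7 higher, by either adjustment). The CYP6 members gave 0.0679 (3 of 4 higher, and 1 lower adjusted over the list alone). Of the 2 glutathione S-transferases GstS1 rose with age (0.22 ± 0.06). The median, mean and tests of a list differed in sign between roles for the endocrine, odorant-binding, oxidative phosphorylation, amine and CYP6 lists, between days for ribosomal proteins, and for role by day for the brood food, immune, venom, muscle, neuronal and cuticle lists, none of which camera called there.

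Libraries were regrouped at random to see how many genes such splits call, with 100 splits in all, the real one included. Only 1 of 100, the real one, gave as many genes as the real split between roles (2031, highest other 12), between roles at day 7 (1366, 34) and at day 26 (1196, 37), between days (1764, 4), between days in nurses (907, 69) and in foragers (1274, 13), for role by day (56, 6) and between colonies (1203, 3). For these, apart from role by day, the shuffles did not give such counts, and 1 of 100 is the smallest share they can give. The shuffles move single libraries as if these were independent. They therefore cannot exclude that libraries alike within a group for another reason raise the real counts. Shuffled roles also lose the role difference itself, which then adds to the spread, so these splits cannot exclude chance for the interaction of role and day. For colony by day 3 of 100 gave as many as the real 3 (highest other 10). Shuffled colonies lose the colony difference too, so chance cannot be excluded there either. The colony by day count was 0 with no filter, with the older dispersions, with the replicate block and with second libraries summed, so it depends on the setting. For colony by role edgeR called 0 genes (512 at an unadjusted p under 0.05, and 12 in DESeq2), a count that all 100 splits must reach (highest other 2), so the splits say nothing about it.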
